A study of Zea mays with 10 samples.

How the data were processed

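Small RNAs (sRNAs) were measured in immature maize cobs about 4 cm long. Total RNA was isolated with TRIzol reagent and libraries were made with Illumina's sRNA preparation. There were 10 libraries in 5 groups, each group with 2 cobs. The B73 parent is an inbred line and served as the father. The T6-9 parent is a B73 line that carries an interchange between chromosomes 6 and 9 and served as the mother. The Rmr1 hybrid is the cross of these parents. The rmr1-1 hybrid comes from the like cross with a T6-9 mother that lacked the Snf2-related protein RMR1, so each hybrid plant carries 1 copy of the mutant allele rmr1-1. The rmr1-1 het is a stock with 1 copy of rmr1-1 that the labels call unrelated to these crosses. Sequencing chemistry was version 3 for both parents and for replicate 1 of the rmr1-1 het, and version 2 for both hybrids and for replicate 2 of the rmr1-1 het.

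The deposited table holds raw read counts per distinct sequence (tag) of 16 to 30 nt in each library, with no normalization. A further deposited column gives, by its name, the number of matches of each tag to the B73 genome; the genome build and the mismatches allowed are not stated, and no genome sequence was at hand to check it. Per the labels, the submitters used CASAVA 1.8 for the version 3 libraries and CASAVA 1.6 for the version 2 libraries, cutadapt with no version given, and Bowtie 0.12.8. Every count was checked to be a whole number and no tag held a letter other than A, C, G and T. The table listed 106738905 tags, of which 68575806 had a single read over all libraries.

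Reads of 18 to 30 nt were analysed. They numbered 123966642 and 109260310 in the B73 parent libraries (replicates 1 and 2), 87477150 and 91221303 in the T6-9 parent, 21272418 and 39773447 in the Rmr1 hybrid, 91788136 and 37799925 in the rmr1-1 het, and 24235495 and 32975489 in the rmr1-1 hybrid. Levels are given in CPM, relative to these reads of the library. At these depths the 95% Wilson interval of a library's 22-nt share reached at most 0.0164 percentage points to either side, and that of its 24-nt share at most 0.02. A count of 0 allows up to 3 counts, which is 0.0242 CPM in the deepest library and 0.141 CPM in the shallowest. Intervals and floors cover counting error only, since reads amplified by PCR are not independent molecules. Where a group had 0 reads in both libraries, a fold is given as a lower bound against 3 counts per library.

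Between replicates, chi-square per degree of freedom over the tested tags ran from 8.27 (Rmr1 hybrid) to 91.3 (T6-9 parent), so no replicates were copies of one library. The correlation of log2 CPM across tags was 0.818 for the B73 parent, 0.6 for the T6-9 parent, 0.852 for the Rmr1 hybrid, 0.78 for the rmr1-1 het and 0.735 for the rmr1-1 hybrid. Tags are not independent replicates. The mean correlation with libraries of other groups was 0.368 for replicate 2 of the T6-9 parent, 0.347 and 0.31 for the rmr1-1 hybrid libraries, and 0.509 to 0.605 for the other libraries.

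Before the data were examined, 4 comparisons, their tests, the list of named sequences and most alternatives were fixed. The T6-9 parent was compared with the B73 parent, the Rmr1 hybrid with the mean of the parents on the log2 scale (mid-parent), the rmr1-1 hybrid with the Rmr1 hybrid, and the rmr1-1 het with the T6-9 parent. Tags with at least 1 CPM in at least 2 libraries were tested, which left 159536. All 10 libraries entered 1 fit in edgeR 4.0.16 (R 4.3.3) with TMM scaling and the quasi-likelihood test, and p-values were adjusted by Benjamini-Hochberg over all tags with a threshold of 0.05. The biological coefficient of variation was 0.603. Many tested tags come from the same loci and overlap, so counts of tags are not counts of loci. The fit was tested on simulated data of 20000 tags in which 100 tags per fold changed: of tags changed 16-fold it recovered 64% in the comparison of the parents, 70% against the mid-parent, 60% between the hybrids and 48% for the het, and of tags changed 4-fold 2%, 9%, 3% and 1%. It made 6, 6, 4 and 3 false calls among 72, 85, 67 and 52 calls. The simulation changed few tags and as many up as down. It therefore does not test the scaling or the error rate where most calls go lower, as between the hybrids.

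Shares of reads by length were compared by exact 2-sided permutation tests, for which the smallest p is 0.333 with 2 against 2 libraries and 0.0667 with 2 against 4. Tags called higher in 1 parent with 0 reads in both libraries of the other parent were called parent-specific, and their summed CPM was followed into the hybrids. A ratio of group means carries an SD propagated from the SDs of both groups.

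Named sequences were 41 conserved miRNAs, a tasiRNA and tRNA fragments in 7 lists (development, auxin and tasiRNA, silencing machinery, nutrient and stress, grass miRNAs, anther phasiRNA triggers, tRNA fragments). They also include, per comparison and direction, the 5 tags with the largest fold change among tags past the threshold whose compared libraries did not overlap and whose mean over all libraries was at least 5 CPM, skipping any that shared 15 or more bases in a row with a tag already chosen. Printing at most the first 2 of these 5 was decided after the data were seen. All other tags are in the counts. The 3 tRNA fragments were not tested as single tags; they were tested as sums over the tags that share their first 18 nt.

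Alternatives tried were scaling by RLE, by total reads and by the reads of the conserved miRNAs, filters of 0.5 and 5 CPM, DESeq2 1.42.0, chemistry version as a covariate, the replicate number as a block, a fit of only the groups compared, size classes taken alone, and leaving out each library in turn. Several sequence properties (GC content, first base and several short motifs) were looked at after the tag fits, and the dinucleotide GG was chosen from them after its values were seen. All results on GG, the test of the difference between the hybrid and het contrasts, the comparison of libraries with and without rmr1-1, the reference level of libraries used for GG, and the split of mid-parent calls by absence from a parent were likewise chosen after seeing the data. Windows along chromosomes, reads with several matches split over their places, and 24-nt reads at the genes rmr1, pl1, b1 and mop1 were planned but are not analysed here, because no genome sequence was at hand. Figures were drawn with matplotlib 3.10.9, and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and pyarrow 21.0.0.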

Results

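The results on GG, the split of mid-parent calls by absence from a parent and the tests limited to tags without GG were chosen only after the results were seen. The tag fits, the shares of reads by length and the parent-specific sums in both hybrids were planned. Shares by B73 matches and by first base, and parent-specific sums in the het, were not in that plan.

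The parents differed in which sRNAs they made, and the T6-9 parent held many sRNAs that lack a match in B73. Of 159536 tags tested, 6876 were higher in the T6-9 parent and 6520 were lower. Of the higher tags 3353 had 0 matches to B73, which is 48.8%, against 3.57% of the lower tags and 5.71% of all tags tested. Among 24-nt reads, the share with 0 matches was 12.3% ± 0.696 (SD, n = 2) in the T6-9 parent and 8.05% ± 1.03 (SD, n = 2) in the B73 parent. The libraries of these groups did not overlap (11.8% and 12.7% against 7.32% and 8.78%).

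These calls come from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. The exact permutation p for the share with 0 matches was 0.333, the smallest that 2 against 2 libraries allow. Without replicate 1 of the T6-9 parent 33382 tags were called, and scaling to conserved miRNA reads called 43398, of which 11.8% were higher. That scaling moved the median log2 difference of all tags by -2.31.

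The size classes of the parents were close. Reads of 22 nt made up 12.6% ± 0.107 (SD, n = 2) of reads in the T6-9 parent and 13.4% ± 0.168 in the B73 parent, a difference of -0.8 percentage points that exceeded the spread between replicates (exact permutation p 0.333). The difference in 24-nt reads, 61.8% ± 2.92 against 64.5% ± 3.35, did not exceed that spread (exact permutation p 0.667). The difference in 22-nt reads changed sign when distinct tags were counted in place of reads (0.343), and among reads without GG it was -0.163 with overlapping libraries.

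Several tags were abundant in a single parent. The 24-nt tag TCTGCGGTCTAGACTGTACGGCGT, with 0 matches to B73, stood at 89.2 CPM ± 44.7 (SD, n = 2) in the T6-9 parent and had 0 reads in the B73 parent. It was at least 3453-fold higher (adjusted p 0.000263). ACTTGTTGGCCTGTAGAATGCGGC, also with 0 matches, was at least 2166-fold higher (55.9 CPM ± 54.5, adjusted p 0.000488), with 94.5 CPM in replicate 2 and 17.4 CPM in replicate 1. In the B73 parent, ACGGGACAGTTCTGGACCGGATGC (1 match) stood at 47.4 CPM ± 4.87 and CAATCTGGCTTATGAAACGGTG (1 match) at 39.2 CPM ± 0.56. Both had 0 reads in the T6-9 parent, so they were at least 1412-fold and 1167-fold lower there (adjusted p 0.000304 and 0.000313).

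Of 41 named sequences 20 were tested, and 5 were higher in the T6-9 parent: miR394 (log2 6.87, adjusted p 0.0327), miR166 (6.36, 0.0219), miR156 (4.30, 0.0162), miR160 (3.77, 0.0375) and miR171d (3.05, 0.0301). Scaled to conserved miRNA reads, miR156 (2.51), miR160 (1.32) and miR171d (-0.02) did not pass the threshold. In a fit of only the groups compared, only miR156 passed it, with adjusted p of 0.0856 for miR394, 0.0893 for miR166, 0.108 for miR171d and 0.137 for miR160. With the chemistry covariate miR160 did not pass it (adjusted p 0.0515). Adjusted over the list alone there were 7, with miR167a and miR167e added. Replicate 2 of the T6-9 parent set the level of several. miR166 stood at 6568 CPM in replicate 2 and 425 CPM in replicate 1, against 6.63 and 97.4 CPM in the B73 parent. Without that library the log2 differences of miR166, miR160, miR171d and miR394 were 2.97, 2.09, 1.78 and 1.05 and none of these 4 passed the threshold. None of the 5 passed it without replicate 1 of the B73 parent, with log2 differences of 3.56 for miR156, 3.03 for miR160, 5.46 for miR166, 3.24 for miR171d and 6.79 for miR394. Without replicate 2 of the B73 parent miR160 (5.34), miR171d (2.88) and miR394 (6.94) did not pass it. Of the called miRNAs 4 belong to the development list (13 of 18 tested) and 1 to the auxin and tasiRNA list (4 of 6 tested, with 3 called over the list alone). The lists for silencing machinery, nutrient and stress, and grass miRNAs had 1 tested member each and no call in any comparison, in edgeR over all tags or over the list alone. Among these 3, only miR827 in the parents had an unadjusted p under 0.05, and DESeq2 called none. Neither anther phasiRNA trigger passed the filter. The 3 tRNA fragments, tested as sums of tags with the same first 18 nt, had 0 calls in edgeR over the 4 comparisons (0 at an unadjusted p under 0.05, not run in DESeq2).

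**Figure D1:**
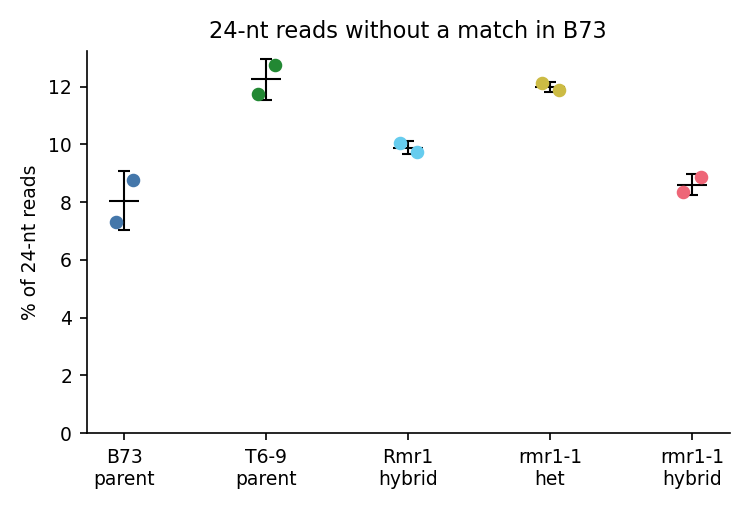
Share of 24-nt reads that have no match in B73 (vertical axis, percent of 24-nt reads) in each library by group (horizontal axis). Points are libraries, the dash is the group mean and the bars are 1 SD (n = 2). The T6-9 parent averaged 12.3%, the Rmr1 hybrid 9.88% and the B73 parent 8.05%.

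Nearly all tags specific to 1 parent were detected in the Rmr1 hybrid, and its share of 24-nt reads without a B73 match lay between those of the parents. That share was 9.88% ± 0.223 (SD, n = 2), against a mid-parent of 10.2% (exact permutation p 0.933). Tags specific to the T6-9 parent (3476) summed to 4586 CPM ± 379 in the hybrid and 8784 CPM ± 1258 in that parent. Tags specific to the B73 parent (4010) summed to 4174 CPM ± 161 in the hybrid and 8330 CPM ± 80.3 in that parent. Of T6-9-specific tags 97.6% were detected in a hybrid library on average, and of B73-specific tags 99.1%. These tags were chosen for 0 reads in the other parent, so a summed level between the parents is largely set by that choice. The filter of 1 CPM in 2 libraries counted the hybrid libraries too, which favours detection there.

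Against the mid-parent, 3409 tags were called higher and 144 lower (edgeR quasi-likelihood, Benjamini-Hochberg). A mid-parent taken on the log2 scale is low for a tag that 1 parent lacks; no fit against an arithmetic mid-parent was run. Of the higher tags 2546 (74.7%) had 0 reads in 1 parent, and their median level was 1.47 times the arithmetic mean of the parents, with quartiles of 1.09 and 2.08. Only 340 exceeded all 4 parent libraries in both hybrid libraries. All 144 lower tags lay below the 4 parent libraries and held GG, but DESeq2 called 1458 lower, a fit of only the groups compared 988 and a fit without replicate 2 of the T6-9 parent 68.

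The count depended on single libraries. Chemistry differs between the parents (version 3) and the hybrid (version 2), and only the 2 het libraries inform a covariate for it, so its effect is poorly known. With that covariate edgeR called 0 tags (6826 at an unadjusted p under 0.05), and DESeq2 without it called 6277. Without replicate 1 or 2 of the B73 parent edgeR called 0 (13844 and 14811 at an unadjusted p under 0.05). Without replicate 1 or 2 of the Rmr1 hybrid it called 7 and 1. Scaled to conserved miRNA reads it called 1460.

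In size classes the hybrid had 67.6% ± 0.982 (SD, n = 2) 24-nt reads, 4.4 percentage points above the mid-parent (exact permutation p 0.2) and 8.63 above it by distinct tags. Its 22-nt share of 12.4% ± 0.784 was -0.563 percentage points from the mid-parent (exact permutation p 0.333), -1.69 by distinct tags, and -1.12 and -0.00876 without replicate 1 or 2 of the hybrid. No named miRNA was called by edgeR or DESeq2 (0 of 20 at an adjusted or unadjusted p under 0.05 in edgeR, and 0 adjusted over the list alone).

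The tag GCTAACTCTGAACTGGGAAGGCAT had 71.7 CPM ± 2.32 (SD, n = 2) in the hybrid, 41.9 and 37.3 CPM in the B73 parent, and 0.0114 and 0 CPM in the T6-9 parent (log2 6.86, adjusted p 0.00732). CGTCGGTAGCGGCTGATGTCTG had 0 reads in the hybrid and 49.7 CPM ± 28.8 (SD, n = 4) in the parents, at least 459-fold lower (adjusted p 0.0313). GACTGCGGCTGCGGCTTCTACAGT had 0 reads against 18.9 CPM ± 15.2, at least 175-fold lower (adjusted p 0.0457). In the rmr1-1 het these 2 lower tags stood at 22.2 and 3.52 CPM in replicate 1 (version 3). In replicate 2 (version 2) they stood at 0.0529 and 0 CPM, and in rmr1-1 hybrids (version 2) at 0 CPM. Their near absence was thus not confined to the cross, and it went with version 2 in every library. With 1 het library per version, chemistry is not separated from other differences between libraries. None of these 3 calls passed the threshold with the chemistry covariate, without replicate 1 (log2 6.90, -14.02 and -12.17) or 2 (6.80, -14.97 and -13.65) of the B73 parent, or without replicate 2 (6.92, -14.81 and -13.40) or 1 (6.83, -14.86 and -13.45) of the Rmr1 hybrid, and the lower 2 also failed without either T6-9 parent library (-14.88 and -14.50, then -13.63 and -12.63).

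Hybrids from a mother without RMR1 had a larger share of 22-nt reads and a smaller share of 24-nt reads than Rmr1 hybrids. Shares of reads do not give amounts of sRNA. Reads of 22 nt made up 22.9% ± 1.76 (SD, n = 2) of reads in rmr1-1 hybrids and 12.4% ± 0.784 in Rmr1 hybrids, 10.5 percentage points more. Reads of 24 nt fell from 67.6% ± 0.982 to 57.4% ± 4.71, a difference of -10.2. In percentage points the gain in 22-nt reads was largest for tags with over 100 matches to B73, already the largest class, which rose from 4.24% to 8.45% of all reads. As a share of 22-nt reads this class moved less, from 33.8% and 34.5% to 37.9% and 36.0% (replicates 1 and 2). Tags of 22 nt with 1 match rose as well, from 2.63% and 2.26% to 3.91% and 4.48% of all reads. Among 22-nt reads, the share beginning with U was 47.6% ± 1.53 against 39.6% ± 0.335.

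In each of these measures the libraries of the groups did not overlap, and the exact permutation p was 0.333, the smallest possible. Both groups were sequenced with version 2 chemistry. Among reads without GG the 22-nt share differed by 11 percentage points. Counted as distinct tags in place of reads, the differences were 3.03 for 22 nt and -1.98 for 24 nt.

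**Figure D2:**
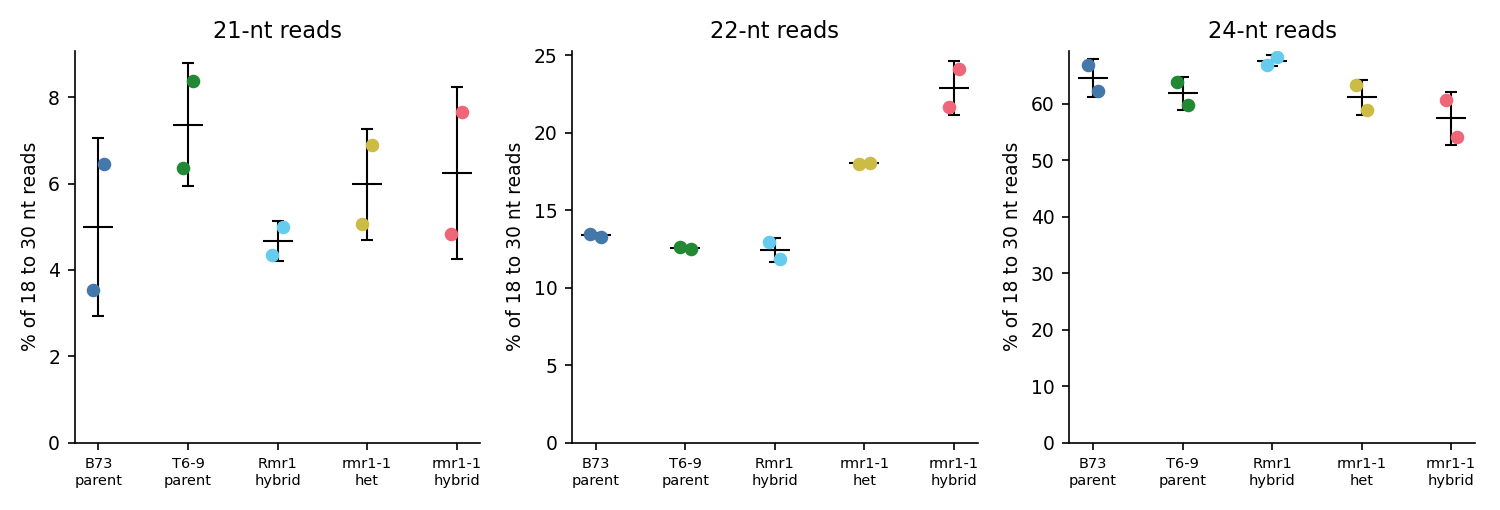
Share of reads of 21, 22 and 24 nt (vertical axes, percent of 18 to 30 nt reads) in each library by group (horizontal axis). Points are libraries, the dash is the group mean and the bars are 1 SD (n = 2). The 22-nt share was 18% and 18.1% in the rmr1-1 het and 21.7% and 24.1% in the rmr1-1 hybrid, against 11.9% to 13.5% in the other libraries.

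Tag by tag, far more tags were called lower than higher in the rmr1-1 hybrid libraries. Relative to Rmr1 hybrids, 39594 tags were lower and 3026 higher (edgeR quasi-likelihood, Benjamini-Hochberg). Of the lower tags 30372 (76.7%) were 24 nt long, and of the higher tags 1808 (59.7%) were 22 nt long. Of the lower tags 99.0% held the dinucleotide GG, against 90.6% of all tags tested. The share called lower was 2.6% of tags without GG, 13.6% with 1, 27% with 2 and 44.5% with 3 or more.

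Complete loss also followed GG. Of 28456 tags with at least 2 CPM in both Rmr1 hybrids, 10.8% had 0 reads in both rmr1-1 hybrid libraries: 0.559% of those without GG and 11.6% of those with it. Of 20062 tags with at least 2 CPM in both T6-9 parent libraries, 1.43% had 0 reads in both rmr1-1 het libraries: 1.31% of those without GG and 1.44% of those with it. This count needs 0 reads in the version 3 library of the het too, so it cannot show a loss confined to version 2 libraries. Median levels fell slightly with GG in the other version 2 libraries too, from 0.37 without GG to -0.14 with 3 or more in replicate 2 of the het and from 0.17 and 0.19 to -0.03 and -0.05 in the Rmr1 hybrids. In replicate 1 of the het (version 3) the median rose from -0.09 to 0.15. Of the other version 3 libraries, those of the B73 parent rose from -0.23 and -0.17 to 0.097 and 0.137. Replicate 1 of the T6-9 parent rose from -0.09 to 0.02, but replicate 2 fell from -0.55 to -0.72.

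A fit of the 14969 tags without GG, with its own scaling, called 23 higher and 207 lower, while the fit of all tags called 726 and 389 of them. The separate scaling moved the median of these tags by -0.57 on the log2 scale. Leaving out single libraries gave 29648 to 40138 calls over all tags, but the number higher was less stable than the number lower. It fell to 375 and 380 without replicate 1 or 2 of the Rmr1 hybrid and to 1283 without replicate 2 of the rmr1-1 hybrid, and was 450 when scaled to conserved miRNA reads and 7092 in DESeq2. The number lower was 28365 to 35714 without 1 library and 40526 in DESeq2.

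**Figure D3:**
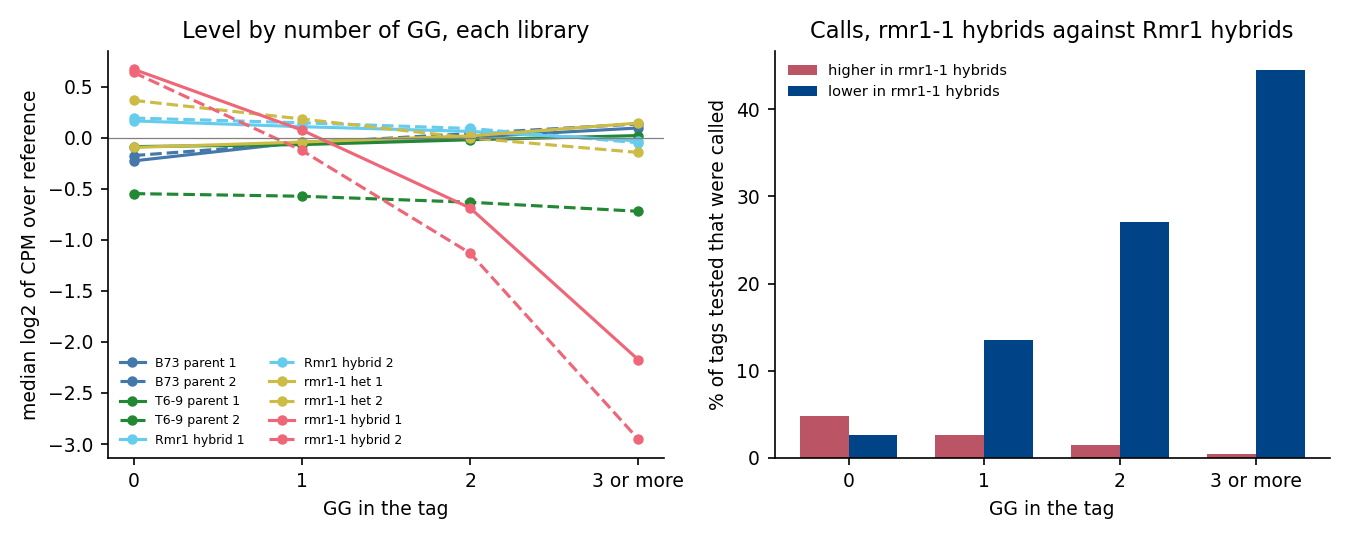
Left, median over tags of log2 CPM in each library over its mean in 7 libraries, which leave out the rmr1-1 hybrids and replicate 2 of the T6-9 parent (vertical axis), by the number of GG in the tag (horizontal axis), 1 line per library. Right, share of tested tags called higher or lower in rmr1-1 hybrids against Rmr1 hybrids (vertical axis, percent) by the number of GG. In rmr1-1 hybrids the median fell from 0.67 and 0.64 without GG to -2.17 and -2.95 with 3 or more, and the share called lower rose from 2.6% to 44.5%.

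The 24-nt tag TCAGACTGGACTGGCTGAGTGCAT had 207 CPM ± 19.0 (SD, n = 2) in Rmr1 hybrids and 0 reads in rmr1-1 hybrids, at least 1928-fold lower (adjusted p 0.00049). CGGGCATGTTGGCACCGGCTG had 199.6 CPM ± 48.2 and 0 reads, at least 1859-fold lower (adjusted p 0.00049). Both hold GG. CCGGAGCTCTGGCGAAGACATC had 49.5 CPM ± 55.6 in rmr1-1 hybrids (10.2 CPM in replicate 1 and 88.8 CPM in replicate 2) and 0 reads in Rmr1 hybrids, at least 457-fold higher (adjusted p 0.000792). TCGACGAACTAAGACTTTCGGCAT, with 0 matches to B73, had 43.5 CPM ± 6.42 against 0 reads, at least 402-fold higher (adjusted p 0.000627). These 2 higher tags were also present in the rmr1-1 het, at 13.2 and 14.4 CPM and at 96.1 and 144 CPM in replicates 1 and 2.

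Among miRNAs, only miR166 was called by edgeR, lower in rmr1-1 hybrids (6.84 CPM ± 2.50 against 127 CPM ± 110, SD, n = 2, log2 -4.37, adjusted p 0.0411). Its sequence holds 2 GG. The other tested members with 2 GG were not called. Of these, miR164 (log2 -1.16), miR319 (-0.73), miR159a (-0.45) and miR169c (-0.09) were lower, and miR168 (1.02) and miR390 (0.785) higher. Of the tested members without GG, only miR827 (-1.82) was lower, and none was called. Adjusted over the list alone 0 of 20 passed (2 at an unadjusted p under 0.05 besides miR166, namely miR172a and miR172e). DESeq2 called miR166, miR172a and miR172e. The edgeR call was lost without replicate 2 of the Rmr1 hybrid (-3.02) and without replicate 1 (-4.02) or 2 (-4.82) of the rmr1-1 hybrid, and when tags with the same first 18 nt were summed (-3.41, adjusted p 0.0727).

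The summed level of T6-9-specific tags was lower in rmr1-1 hybrids than in Rmr1 hybrids, and that of B73-specific tags was higher. T6-9-specific tags summed to 1990 CPM ± 23.1 (SD, n = 2) in rmr1-1 hybrids and 4586 CPM ± 379 in Rmr1 hybrids, a ratio of 0.434 ± 0.0362. The ratio was 0.335 ± 0.0922 for 24-nt tags. For 22-nt tags it was 0.948 ± 0.471 with overlapping groups (891 and 431 CPM in rmr1-1 hybrid replicates 1 and 2, 728 and 666 CPM in Rmr1 hybrids, exact permutation p 1). B73-specific tags summed to 6840 CPM ± 819 against 4174 CPM ± 161, a ratio of 1.64 ± 0.206, with 3.34 for 22-nt tags and 1.03 for 24-nt tags. Tags of both sets were lost: 39.4% of T6-9-specific and 15% of B73-specific tags had 0 reads in both rmr1-1 hybrid libraries, against 1.01% and 0.499% in both Rmr1 hybrid libraries. In the het, T6-9-specific tags stood at 0.4 ± 0.0761 of their level in the T6-9 parent, where they were chosen. B73-specific tags stood at 4593 CPM ± 106 in the het, with 78.8% detected on average, against 8330 CPM ± 80.3 in the B73 parent. A stock other than the B73 parent thus held many of them, so a maternal contribution to them in rmr1-1 hybrids is not separated from the paternal one. For both sets the groups did not overlap (exact permutation p 0.333).

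Tags without GG gave other ratios. Over 283 T6-9-specific tags without GG the ratio was 0.946 ± 0.168, and over 389 B73-specific tags without GG it was 3.26 ± 0.266. Even so, 17.7% of these T6-9-specific tags had 0 reads in both rmr1-1 hybrid libraries, against 0.257% of these B73-specific tags. In Rmr1 hybrids 0% of either set had 0 reads in both libraries.

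**Figure D4:**
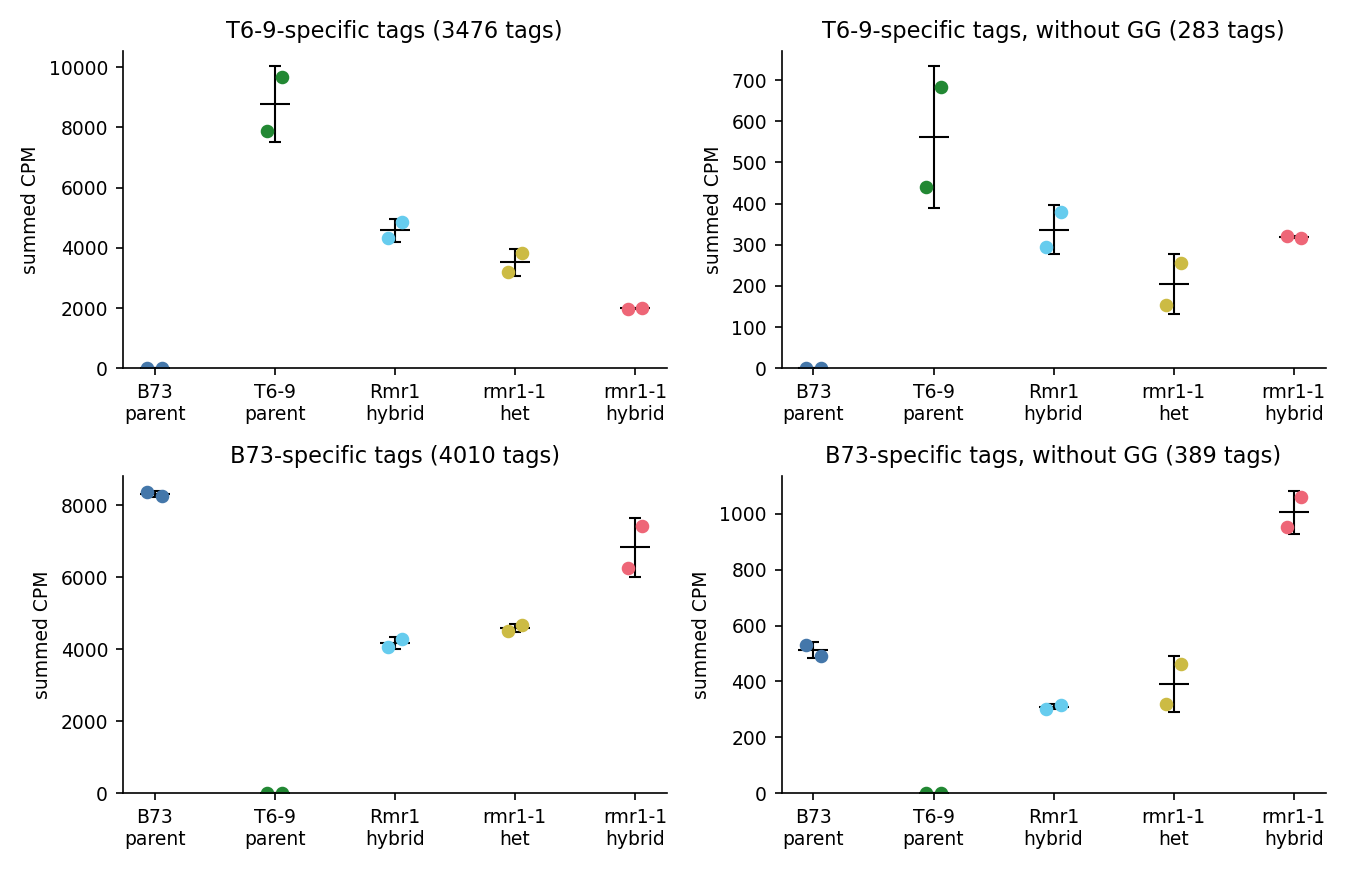
Summed CPM of parent-specific tags (vertical axes) in each library by group (horizontal axis), for all such tags on the left and for those without GG on the right. Points are libraries, the dash is the group mean and the bars are 1 SD (n = 2). T6-9-specific tags averaged 4586 CPM in Rmr1 hybrids and 1990 CPM in rmr1-1 hybrids, and those without GG 337 and 319 CPM.

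The rmr1-1 het also had a larger share of 22-nt reads than the T6-9 parent, while its share of 24-nt reads did not differ beyond the spread between replicates. Its 22-nt share was 18% ± 0.0658 (SD, n = 2) against 12.6% ± 0.107, 5.45 percentage points more. Tags with over 100 matches to B73 again took part, at 6.04% of all reads against 3.7%. The 24-nt share was 61.1% ± 3.06 against 61.8% ± 2.92, and the share beginning with U among 22-nt reads was lower, at 35% ± 1.13 against 38.9% ± 2.32.

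The exact permutation p was 0.333 for the 22-nt share and 0.667 for the 24-nt share. The version 3 library of the het had a 22-nt share of 18%, against 12.7% and 12.5% in the T6-9 parent libraries of the same chemistry. Counted as distinct tags, the differences were 1.14 for 22 nt and 5.21 for 24 nt, against -0.719 for 24 nt by reads. The U share among reads without GG differed by 0.249, the other way round.

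In the het, 6289 tags were higher and 3053 lower than in the T6-9 parent (edgeR quasi-likelihood, Benjamini-Hochberg), with shares called that varied little with GG (3.65% to 4.09% higher and 1.58% to 2% lower from 0 to 3 or more). Of the higher tags 2129 were 22 nt long and 3370 were 24 nt long. Without replicate 1 of the T6-9 parent 28618 tags were called. DESeq2 called 7144 higher and 6273 lower, edgeR with the chemistry covariate 5558 and 1695, and edgeR without replicate 1 or 2 of the het 1569 and 1718 lower.

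TCGACGAACTAAGACTTTCGGCAT stood at 119.8 CPM ± 33.5 (SD, n = 2) in the het and had 0 reads in the T6-9 parent, at least 3567-fold higher (adjusted p 0.00063). AGGCCGGTGATGTAGAGTGCAT had 53.6 CPM ± 2.37 against 0 reads, at least 1595-fold higher (adjusted p 0.000928). TTCGTCTGTACGACCGAACCGG had 175 CPM ± 199.9 in the T6-9 parent (33.6 CPM in replicate 1 and 316 CPM in replicate 2) and 0 reads in the het, at least 3124-fold lower (adjusted p 0.000612). ATCCACTGTATGGCTTCGGCGG had 117 CPM ± 115 (36.2 and 198 CPM) against 0 reads, at least 2094-fold lower (adjusted p 0.000576).

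For miRNAs, edgeR called only miR171d, lower in the het (10.5 CPM ± 8.10 against 80.9 CPM ± 56.4, SD, n = 2, log2 -3.24, adjusted p 0.0297). Adjusted over the list alone 4 were lower, namely miR171d, miR160, miR166 and miR394. The miR171d call was lost without replicate 2 of the T6-9 parent (-1.98), without replicate 1 (-2.62) or 2 (-4.26) of the het, when scaled to conserved miRNA reads (-1.60), with the chemistry covariate (-4.26, adjusted p 0.06) and in a fit of only the groups compared (-3.24, adjusted p 0.143).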

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

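All tests of differences between contrasts below, and all tests on GG, on chemistry, on lost molecules, on shortened reads and on reads not 24 nt long, were chosen only after the results were seen. The tests of abundant tags, of base composition, of loci missing from the rmr1-1 stock and of a general 24-nt loss were written before.

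The change from Rmr1 to rmr1-1 hybrids differed from the change from the T6-9 parent to the rmr1-1 het. Tested as a difference of contrasts (edgeR quasi-likelihood, Benjamini-Hochberg), 32163 tags lay lower and 1806 higher in the hybrid contrast. Of the lower tags 98.6% held GG. Among the 14969 tags without GG, 292 lay lower and 44 higher when fitted alone, and 457 and 385 in the fit of all tags. The tags TCAGACTGGACTGGCTGAGTGCAT and CGGGCATGTTGGCACCGGCTG differed by -16.35 and -16.13 on the log2 scale. Both are at 0 reads in both rmr1-1 hybrid libraries, so these fitted values are no bounds. The miRNAs miR167a and miR171d differed by 3.52 and 3.65 (adjusted p 0.0369 and 0.0293). Both contrasts rest on groups of 2 libraries from different stocks.

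The first pattern is the larger 22-nt share in rmr1-1 hybrids than in Rmr1 hybrids. A few abundant tags do not account for it, since the difference without the 100 most abundant tags was 9.64 percentage points, nor does a loss of reads with GG, since it was 11 among reads without GG. Chemistry was version 2 in both groups, and the 2 het libraries, 1 of each chemistry, differed by 0.093 percentage points. Shortened 24-nt reads would lower the U share of 22-nt reads, which was higher by 7.999 percentage points. A fall of 24-nt reads alone would leave the 22-nt share of the other reads alike, which was higher by 15.5. That value cannot exclude a joint fall of 23-nt and 24-nt reads as a part of the pattern. Of reads not 24 nt long, 23-nt reads made up 26.4% ± 1.93 (SD, n = 2) in rmr1-1 hybrids and 40.9% ± 1.37 in Rmr1 hybrids. The rmr1-1 genotype of the mother remains a possible explanation, as do other differences between the maternal stocks, which were not tested.

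For the second pattern, the large number of tags called lower in rmr1-1 hybrids, loss of molecules in libraries of low complexity would strike each library apart, but tags missing from both were 5.09 times as frequent as the product of the shares missing from each, taken within strata of level, GG and length. Loci missing from the maternal stock cannot explain the 54.2% of these tags that had at least 1 CPM in both B73 parent libraries, since the B73 father gives its copy to both hybrids. A loss of tags that hold GG may explain most calls, since 2.6% of tags without GG were called lower and the share rose with each further GG. Base composition as such stays open: the lowest share called lower over GC quintiles and first bases was 9.49%, between the bounds of 5% and 10% set beforehand. From the lowest GC quintile to the highest the share called lower was 9.49%, 19%, 24.9%, 30.2% and 40.6%. It thus rose with GC content too, and GG was not separated from GC content. A step of library preparation is not separated from the genotype or stock of the mother. The rmr1-1 het, also with 1 copy of rmr1-1, lost 1.31% of tags without GG and 1.44% of tags with GG relative to the T6-9 parent. These shares cannot show a loss confined to version 2 libraries, since a lost tag needs 0 reads in the version 3 library of the het too. The median of the version 2 library of the het fell with GG, from 0.37 to -0.14.

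The third pattern is the lower level of T6-9-specific tags in rmr1-1 hybrids. A general loss of 24-nt tags falls short, since 24-nt T6-9-specific tags were absent 2.07 times as often as 24-nt tags of both parents at the same level. Loss of tags with GG falls short as the whole cause: 24-nt T6-9-specific tags without GG were absent 19.6 times as often as matched tags without GG (95% interval 14.3 to 26.4, tags of one locus not independent), a test chosen after a first one on summed levels. Without GG the T6-9-specific ratio was 0.946, but B73-specific tags rose as well, so the T6-9-specific ratio over the B73-specific ratio stayed at 0.29 ± 0.0567 against 0.265 ± 0.04 over all tags. A region missing from the rmr1-1 stock stays open: the share absent among 24-nt tags was 1.71 times that among 22-nt tags, and the bound of 1.5 set beforehand lies inside its 95% interval of 1.47 to 2, an interval added after the ratio was seen. This ratio cannot decide the question. B73-specific tags, which the B73 father can supply, were also absent more often at 24 nt (17.2%) than at 22 nt (8.64%).

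Reads of 16 and 17 nt are in the table and entered no comparison. They numbered 1378666 over all libraries, from 0.0158% to 0.461% of a library's reads.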

How the results depend on the processing

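Alternatives on GG were chosen after seeing the data; the rest were fixed before the data were examined. A value here is a number of tags called unless stated otherwise, and the cause of a change was not tested unless named. Counts under RLE and total-read scaling and with the replicate number as a block (14439 for the parents, 4453 against the mid-parent, 44184 between hybrids, 10051 for the het) stayed within 1.5 times. The number ties no libraries across groups in the labels, and deviations of like-numbered libraries correlated at -0.208 to 0.566. In the order parents, mid-parent, hybrids and het, a filter of 5 CPM gave 1780, 982, 6330 and 1367 (fewer tags tested), 20 to 22 nt tags 4868, 1067, 6157 and 3807, and tags without GG 1129, 108, 230 and 799. A filter of 0.5 CPM gave 30125, 82839 and 19935 for the parents, hybrids and het (more tags tested), and 24-nt tags alone 7693 and 4928 for the parents and het. Scaling to conserved miRNA reads gave 43398 for the parents (median log2 shift -2.31) and 1460 against the mid-parent, moved the median by -0.89 for the hybrids and 0.95 for the het, and turned the log2 difference of miR171d in the parents to -0.01865. RLE moved the median by -0.12 against the mid-parent and 0.20 for the hybrids, and total-read scaling moved the last 3 medians by 0.19, 0.16 and 0.14. Against the mid-parent DESeq2 called 6277 and the chemistry covariate 0. Leaving out 1 library gave 9809 to 33382, 0 to 2720, 29648 to 40138 and 6657 to 28618. A lone library left in a group was assumed to vary like the others. Of differences in the 22-nt share, in percentage points, distinct tags gave 0.343 (sign changed), -1.69, 3.03 and 1.14, reads without GG -0.163 for the parents and 6.38 for the het, and 5.25 for the het without the 100 most abundant tags. Against the mid-parent, leaving out 1 library gave -1.12 to -0.00876. For the 24-nt share distinct tags gave 8.63, -1.98 and 5.21 for the last 3 comparisons. The U share of 22-nt reads in the het became 0.249 among reads without GG. The T6-9-specific ratio was 0.335 with 24-nt tags, 0.387 with TMM-scaled sizes and 0.946 without GG, and the B73-specific ratio 1.03 and 3.26 with 24-nt tags and without GG. Of alternatives for named tags, 388 kept direction and threshold and 12 fell short of the threshold; leaving out 1 library, 136 kept both and 44 fell short. For list members 875 kept both, 11 fell short, 13 newly passed and 1 changed sign; leaving out 1 library, 335 kept both, 18 fell short and 7 newly passed. A sign change of a member called in neither setting counts as kept. The planned shares of 20, 21 and 23 nt were set aside after the data were seen. The 23-nt share was not minor, at 13.7% ± 0.753 (SD, n = 2) in the B73 parent and 13.9% ± 0.613 in the T6-9 parent. It was 13.3% ± 0.0425 in Rmr1 hybrids, 11.3% ± 2.07 in rmr1-1 hybrids and 12.2% ± 0.506 in the rmr1-1 het. Windows along chromosomes and genes were not run, for want of a genome sequence.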

Other observations

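The test of libraries with and without rmr1-1 was chosen after the 22-nt shares were seen. The 4 libraries with 1 copy of rmr1-1, 2 hybrid and 2 het, had a 22-nt share of 20.5% ± 2.99 (SD, n = 4), and the 6 libraries without it 12.8% ± 0.586 (SD, n = 6). The groups did not overlap, with a lowest value of 18% and a highest value of 13.5%. The libraries come from 5 stocks or crosses, and an exact permutation test over the 5 group means gave p 0.1, the smallest that 2 against 3 groups allow, so this split decides nothing about rmr1-1. For the 24-nt share the groups overlapped (59.3% ± 3.90 against 64.7% ± 3.28).

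Tags that begin with a tRNA-Ala fragment summed to 59.3 CPM in the B73 parent, 74.9 CPM in the T6-9 parent, 131 CPM in the Rmr1 hybrid, 84.2 CPM in the rmr1-1 het and 198 CPM in the rmr1-1 hybrid (94.9 and 301 CPM in its replicates). Summed over tags with the same first 18 nt, edgeR did not call it between the hybrids (log2 0.44, adjusted p 0.699) or against the mid-parent (log2 0.76, adjusted p 0.831). The exact sequences of miR395, miR1432, miR2275 and tasiR-ARF had no read in any library. Tags with the first 18 nt of tasiR-ARF averaged 1.14 CPM ± 1.23 (SD, n = 2) in the T6-9 parent, 0.0355 CPM in the B73 parent, 0.22 CPM in the Rmr1 hybrid, 0.289 CPM in the rmr1-1 het and 0.242 CPM in the rmr1-1 hybrid.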
